A study of Rattus norvegicus with 10 samples.

How the data were processed

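The series holds 10 rat lung RNA-seq libraries in 2 groups of 5, MOD 1 to 5 and XBS 1 to 5, and each library took its group and replicate number from its title. Per the labels' protocols, total RNA was isolated with Trizol, messenger RNA was purified and fragmented, and libraries were made with adapter ligation and PCR; whether strand was kept is not given in the sources used here. The labels also list the human bronchial cell line 16HBE, and the submitters' processing notes name the builds hg38, GRCh38 and mm10, which are human and mouse, while the deposited table has rat Ensembl gene identifiers. The aligner, the counter, the annotation release and the rat genome build are not given in the sources used here. Gene positions are printed as the table gives them.

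Per the file headers, the authors deposited 1 table with a read count and an FPKM value per gene and library. The deposited counts were whole numbers with different totals, not normalized. The deposited FPKM values equalled the count divided by gene length and library total (largest relative deviation 8.82e-08), so they added no further information and were left out. The table had 22250 genes. Without strand, reads of overlapping and antisense genes cannot be told apart, and near-identical paralogues may share reads. Kdm5d, on the Y chromosome, had 875 to 1076 counts in every library. Pairs of libraries within a group differed by more than sampling noise (smallest chi-square per degree of freedom 9.46 over genes with at least 20 counts), so all libraries were counted as separate. Correlations of log2 CPM were 0.929 to 0.981 within groups and 0.941 to 0.982 between groups.

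Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 14320 genes holding 99.921% of the counts. They were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) in R 4.3.3, XBS over MOD, with Benjamini-Hochberg adjustment over these genes and a threshold of 0.05. Every adjusted p of a single gene is from edgeR unless another tool is named. CPM values are counts scaled to the TMM-adjusted library size, given as mean ± SD; standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. Totals of 11998979 to 15518929 counts per library set the precision, and genes near 3 counts could not be compared.

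The 51 gene lists were written before the data were examined, as were the tests and the alternatives, except where the text says otherwise. The 49 lists with at least 3 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with prior count 2), with camera at an estimated correlation and with fry beside it. A list's score in a library is the mean over its tested members of log2 CPM centred on each gene's mean; scores of the passing lists, both clock arms and 3 neutrophil lists were compared by an exact two-sided permutation test over all assignments of the 10 libraries. Genes that rose or fell passed the threshold over all genes tested; counts adjusted over the list alone are given beside them.

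Named genes were fixed by rule: the members of both clock arms and Mpo, the 12 genes of smallest p past the threshold in each direction that have a proper symbol (filled to 5 with genes that did not pass), the 4 members of smallest p of each passing list, and the 2 of smallest p of the neutrophil, cytokine, interleukin 17, type 2 and mucus lists. Of the 101 genes it took, 99 were tested; Mpo was not, and 1 gene is not reported here.

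Alternatives were DESeq2 1.42.0, RLE and upper quartile scaling, no filter, a filter of at least 1 CPM in 5 libraries, limma voom with sample weights, the replicate number as a block, thresholds with a 2-fold change, and leaving out each library in turn; for scores, a prior count of 0.5 and the median over members. Leaving out XBS 2 and XBS 3, leaving out MOD 4 and XBS 5, an adjusted p under 0.1 and an airway covariate were added after seeing the data. The airway covariate, or airway score, is the mean of a library's club and ciliated cell scores. In simulated counts for XBS against MOD with 14320 genes, of which 200 were changed, edgeR recovered 40.3%, 83.6% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold with 3.38% false calls, and DESeq2 56.7%, 86.6% and 95.5% with 18% false calls. The simulation drew each gene independently and gave the libraries no shared structure, so these rates may not hold for the real libraries. Other splits of the libraries were tested for 100 of the possible assignments, and for 40 by DESeq2.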

Results

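Messenger RNA was measured by RNA sequencing in 10 rat lung libraries, 5 named MOD and 5 named XBS. The design text describes neutrophilic asthma induced in rats with lipopolysaccharide, a bacterial cell wall component, and ovalbumin, an egg protein used as allergen, followed by administration of a formula abbreviated SP. It names NR1D1, a nuclear receptor that represses transcription within the circadian clock, as the upregulated gene that was followed up. The labels expand neither MOD nor XBS and tie neither name to SP, so the comparison is given as XBS against MOD. The deposited table held 22250 genes, of which 3889 had 0 counts in every library. Total counts ranged from 11998979 in XBS 1 to 15518929 in XBS 4, so that 3 counts corresponded to between 0.193 and 0.25 CPM, the read count scaled to library size, counting error only. The labels do not say that the 5 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

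The comparison asked which lung genes differed between the groups, with Nr1d1 as the gene of interest, and circadian clock genes differed by up to 6.52-fold. Nr1d1 averaged 13.5 ± 8.67 CPM (SD, n = 5) in MOD and 87.8 ± 38.8 CPM (SD, n = 5) in XBS, a 6.52-fold difference with a log2 fold change of 2.70 ± 0.43 (SE). Every XBS library (44.7 to 147.1 CPM) lay above every MOD library (6.95 to 28.1 CPM). Its paralogue Nr1d2 was 2.83-fold higher in XBS, at 134 ± 27.6 against 47.2 ± 19.4 CPM (SD, n = 5). Dbp, a transcription factor driven by the clock, was 3.98-fold higher and the period gene Per3 2.34-fold higher. None of these genes passed the threshold over all 14320 genes tested by edgeR, with adjusted p = 0.0759 for Nr1d1 and for Nr1d2, 0.104 for Dbp and 0.124 for Per3. The call for Nr1d1 depended on the tool, with adjusted p = 7.13e-09 by DESeq2 and 0.0362 by limma voom with sample weights, and on MOD 3, without which edgeR gave 0.0213. Nr1d1 (ENSRNOG00000009329) lies on chromosome 10 from 86683875 to 86690815 and Per1 (ENSRNOG00000007387) on chromosome 10 from 55687050 to 55695994 in the deposited table, whose genome build is not given in the sources used here.

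**Figure D1:**
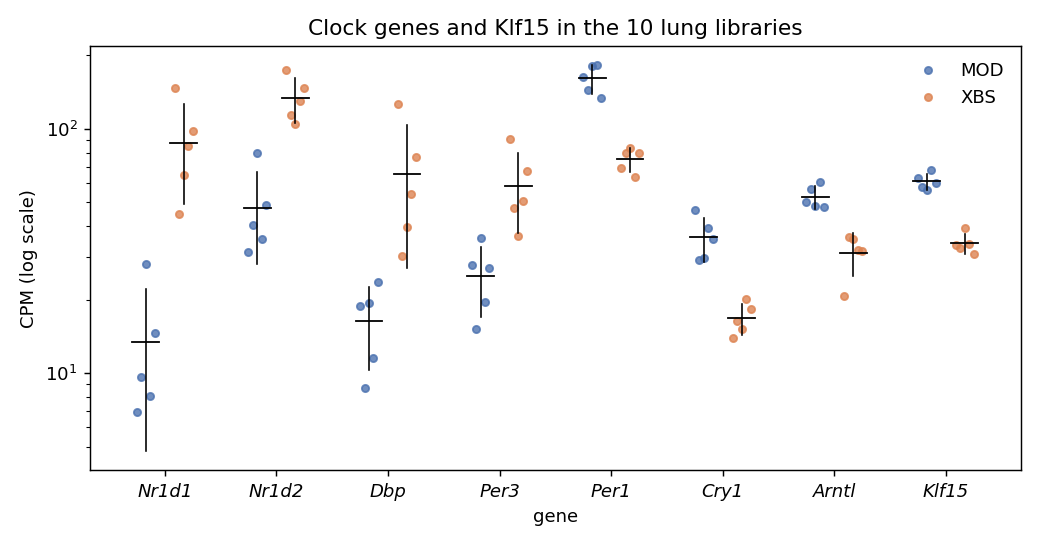
CPM (log axis) of 8 genes in each library, MOD in blue and XBS in orange, with a horizontal line at the group mean and a vertical line of 1 SD to either side (n = 5 per group). For each of these genes no library of one group lies inside the range of the other, and Per1, Cry1, Arntl and Klf15 are lower in XBS. The other tested members of both clock arms are not shown, and their groups overlapped.

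Genes of the opposite phase of the clock were lower in XBS. Cry1, a repressor of the clock, fell 2.14-fold, from 36.0 ± 7.34 to 16.8 ± 2.42 CPM (SD, n = 5, adjusted p = 0.0302). Arntl, the partner of CLOCK in the activating complex, was 1.69-fold lower (adjusted p = 0.0858). Clock, Npas2 and Nfil3 were 1.20-fold, 1.23-fold and 1.21-fold lower, with groups that overlapped. The list named the positive arm of the clock held 5 tested members, Arntl, Clock, Npas2, Nfil3 and Cry1, and so included the repressor Cry1. Of these 5, 0 rose, 1 fell (Cry1) and 4 did not pass, with 3 lower when adjusted over the list alone. As a list the positive arm was lower in XBS by camera (adjusted p = 4.92e-05), but not with an estimated correlation (adjusted p = 0.214 with an estimated correlation). Of the 12 tested members of the negative arm, 10 had a positive fold change. Of these 12, 0 rose, 1 fell and 11 did not pass, and adjusted over the list alone 6 were higher and 1 lower. The groups overlapped for Per2 (1.23-fold higher), Tef (1.32-fold), Ciart (2.29-fold), Hlf (1.12-fold), Cry2 (1.10-fold), Bhlhe41 (1.09-fold) and Usp2 (1.10-fold lower). The list was higher in XBS by camera (adjusted p = 0.00415), but not with an estimated correlation (adjusted p = 0.588) or by fry (adjusted p = 0.232). Its score overlapped between the groups, with XBS 2 (-0.0956) below MOD 3 (-0.0597) (exact permutation p = 0.0159). The 1 member that fell was Per1, a period gene that also responds to glucocorticoids, at 161 ± 21.4 CPM in MOD and 75.0 ± 8.48 CPM in XBS (SD, n = 5; 2.14-fold lower, adjusted p = 0.00455). The score of the negative arm minus that of the positive arm averaged -0.606 ± 0.305 in MOD and 0.606 ± 0.534 in XBS (SD, n = 5), a difference of 1.21 on the log2 scale. The highest MOD library stood at -0.235 and the lowest XBS library, XBS 2, at -0.0157 (two-sided exact permutation p = 0.00794, the smallest that the assignments of 10 libraries can give). The gap between these libraries was smaller than the SD within either group.

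Over all genes tested, 11 passed an adjusted p of 0.05, 4 higher and 7 lower in XBS. The genes that rose were Irf5, Bub1, Lilrb3 and Mki67. Irf5, a transcription factor of innate immune signalling, rose 1.61-fold, from 30.8 ± 3.36 to 49.6 ± 4.02 CPM (SD, n = 5, adjusted p = 0.0302). Bub1, a mitotic checkpoint kinase, rose 1.60-fold (adjusted p = 0.0412), and Mki67, which encodes the proliferation marker Ki-67, rose 1.72-fold (adjusted p = 0.0445). Lilrb3, an inhibitory receptor of leukocytes, rose 2.84-fold from 5.87 ± 1.46 to 16.7 ± 4.37 CPM (SD, n = 5, adjusted p = 0.0412); it belongs to a family of near-identical receptors whose reads the counting could have split. The next gene in this direction, the condensin subunit Ncapd2, did not pass (1.39-fold, adjusted p = 0.0734). Besides Per1 and Cry1, the genes that fell were Klf15, Klf5, Cyp4b1, Inpp5b and Nfkbia. Klf15, a transcription factor induced by glucocorticoids, fell 1.79-fold, from 60.9 ± 4.56 to 34.0 ± 3.25 CPM (SD, n = 5, adjusted p = 0.00455). Klf5, a related factor of epithelial cells, fell 1.53-fold (adjusted p = 0.00714). Cyp4b1, a cytochrome P450 abundant in lung, fell 1.58-fold, from 395 ± 11.2 to 249 ± 25.7 CPM (SD, n = 5, adjusted p = 0.0104). The phosphoinositide phosphatase gene Inpp5b fell 2.68-fold (adjusted p = 0.0412), and Nfkbia, which encodes an inhibitor of NF-kB, fell 1.79-fold (adjusted p = 0.0445). Each of the 11 genes had groups that did not overlap, as had 393 of all tested genes (2.74%, against 0.794% by chance).

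The number of genes depended on the test. At an unadjusted p under 0.05, edgeR gave 1888 genes where 716 would be expected by chance, and DESeq2 gave 348 genes past its adjusted threshold, 202 higher and 146 lower, the 11 included. Without MOD 2, MOD 3, MOD 4, XBS 1, XBS 2 or XBS 3 singly the count was 4 to 7, and with 2 libraries left out, chosen after seeing the data, it was 3 (without XBS 2 and XBS 3) or 0 (without MOD 4 and XBS 5, with 1340 genes at an unadjusted p under 0.05 by edgeR). Per1, Klf15, Klf5 and Cyp4b1 passed whichever single library was left out, and each of the other 7 genes was lost in 4 to 9 of the 10 runs. With the replicate number as a block, 1 gene passed by edgeR and 0 of the 11 (2070 genes at an unadjusted p under 0.05).

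Genes induced by glucocorticoids were lower in XBS as a list. Of 16 tested members 13 had a negative fold change; 0 rose, 2 fell (Per1 and Nfkbia) and 14 did not pass, and adjusted over the list alone 10 were lower (camera adjusted p = 9.97e-09; adjusted p = 0.148 with an estimated correlation). Tsc22d3, the glucocorticoid-induced leucine zipper, was 1.89-fold lower in XBS (433 ± 77.3 against 229 ± 49.9 CPM, SD, n = 5, adjusted p = 0.0858), and Errfi1, an inhibitor of EGF receptor signalling, 1.70-fold lower (adjusted p = 0.0858). The list score was lower in every XBS library than in any MOD library, by 0.53 on the log2 scale (exact permutation p = 0.00794, and 0.0333 adjusted over 21 list scores). Most of these 21 lists were taken because they passed by camera on the same libraries, which the adjustment does not count. The list of rhythmic output genes shares Tsc22d3, Cdkn1a, Fkbp5 and Pdk4 with the glucocorticoid list. It was also lower (camera adjusted p = 0.000615, and 0.272 with an estimated correlation). Of its 11 tested members 0 rose, 0 fell and 11 did not pass, with 3 lower when adjusted over the list alone; Cdkn1a, a cell cycle inhibitor, was 1.94-fold lower (adjusted p = 0.0858).

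Cell cycle genes were higher in XBS. Of 17 tested members 15 had a positive fold change; 2 rose (Bub1 and Mki67), 0 fell and 15 did not pass, and adjusted over the list alone 13 were higher (camera adjusted p = 3.1e-11; adjusted p = 0.148 with an estimated correlation). Top2a, a DNA topoisomerase, was 1.56-fold higher and Mcm5, part of the replicative helicase, 1.44-fold higher, both with adjusted p = 0.0854. Every XBS library scored above every MOD library, with a difference of 0.456 on the log2 scale (exact permutation p = 0.00794). XBS 5, one of the libraries with a high score, also had the highest score for thymus and lymph node genes (2.04, against -0.802 to 0.572 in the other libraries).

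Several lists of innate immune genes were higher in XBS without a single member passing over all genes. The interferon response list had a positive fold change in all 18 tested members (0 rose, 0 fell, 18 did not pass; 3 higher when adjusted over the list alone; camera adjusted p = 2.88e-06; adjusted p = 0.588 with an estimated correlation). Irf7, a master regulator of interferon genes, was at 83.4 ± 31.0 CPM in MOD and 176 ± 63.2 CPM in XBS (SD, n = 5, adjusted p = 0.228), and the chemokine gene Cxcl10 was 2.24-fold higher (adjusted p = 0.187). The score overlapped between the groups, with XBS 4 at -0.528 and MOD 4 at 0.274 (exact permutation p = 0.0635). The inflammasome list had a positive fold change in all 10 tested members, and 4 were higher when adjusted over the list alone (0 rose, 0 fell, 10 did not pass; camera adjusted p = 0.000261; adjusted p = 0.278 with an estimated correlation). Aim2, a sensor of cytosolic DNA, was 2.32-fold higher (adjusted p = 0.113), Il1b, which encodes interleukin-1 beta, 1.64-fold (adjusted p = 0.162) and Nlrp3, a sensor protein, 1.45-fold (adjusted p = 0.222). The inflammasome score was higher in every XBS library (difference 0.39, exact permutation p = 0.00794).

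Of the marker lists of leukocytes, 5 were also higher in XBS by camera, and none held with an estimated correlation; NK and cytotoxic, alveolar macrophage, plasma cell and mast cell lists did not pass by camera (adjusted p = 0.0759, 0.125, 0.137 and 0.758). The monocyte and interstitial macrophage list gave adjusted p = 0.00414 (11 of 13 members positive; 0 rose, 0 fell, 13 did not pass; 4 higher adjusted over the list alone; adjusted p = 0.615 with an estimated correlation), with the complement gene C1qb 1.43-fold higher (adjusted p = 0.154). Without MOD 1 this list was not past the threshold (adjusted p = 0.0971). Neutrophil markers gave adjusted p = 0.0168 (18 of 20 members positive; 0 rose, 0 fell, 20 did not pass; 0 adjusted over the list alone; adjusted p = 0.588 with an estimated correlation). Ncf4 and Ncf1, subunits of the phagocyte NADPH oxidase, were 1.39-fold and 1.36-fold higher (adjusted p = 0.297 and 0.382), and the neutrophil score overlapped between the groups (difference 0.262, exact permutation p = 0.143). The neutrophil call was lost without MOD 1, XBS 2 or XBS 3, with adjusted p up to 0.125. In runs chosen after seeing the data, its median log2 fold change went from 0.37 to 0.063 without XBS 2 and XBS 3 (adjusted p = 0.488) and to 0.15 with the airway score as a covariate (adjusted p = 0.23). B cell, dendritic cell and MHC class II, and T cell lists each gave adjusted p = 0.0399, with 10 of 11, 10 of 13 and 14 of 16 members positive. In these lists 0 members rose, 0 fell, and 11, 13 and 16 did not pass; adjusted over the list alone 0, 1 and 0 were higher. With an estimated correlation they gave adjusted p = 0.663, 0.588 and 0.644. Of the 10 runs without a single library, 5, 7 and 6 lost these calls, and without XBS 5 the median log2 fold change of the B cell list went from 0.40 to 0.13 (adjusted p = 0.204). Among their members, Cd22 of B cells was 1.46-fold higher (adjusted p = 0.265), the integrin gene Itgax 1.58-fold higher (adjusted p = 0.162) and Cd8a of cytotoxic T cells 1.87-fold higher (adjusted p = 0.265). Cd8a stood at 42.0 to 52.0 CPM in XBS 1, XBS 2 and XBS 3. In XBS 4 (15.8 CPM) and XBS 5 (21.6 CPM) it lay within the MOD range of 15.4 to 23.7 CPM.

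**Figure D2:**
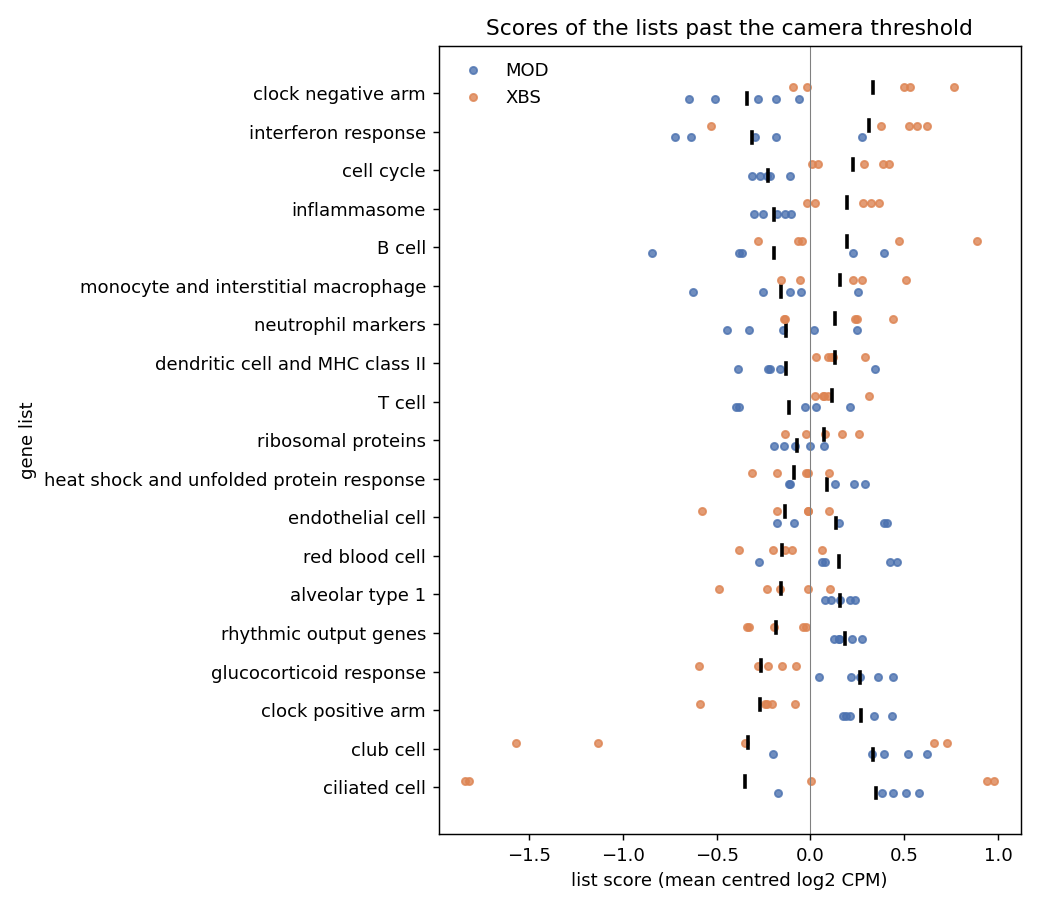
Score of each of the 19 lists past the camera threshold in each library (mean centred log2 CPM of the list's tested members), MOD in blue and XBS in orange, with a vertical line at each group's mean (n = 5 per group). The groups do not overlap for cell cycle, inflammasome, rhythmic output, glucocorticoid response and clock positive arm lists, while 2 XBS libraries lie far below the others for club and ciliated cell genes.

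Alveolar type 1 and endothelial lists were lower in XBS, while alveolar type 2, fibroblast and matrix, and smooth muscle lists did not pass by camera (adjusted p = 0.816, 0.735 and 0.695). All 13 tested alveolar type 1 genes, of the flat cells of gas exchange, had a negative fold change (0 rose, 0 fell, 13 did not pass; 5 lower when adjusted over the list alone; camera adjusted p = 2.72e-05; adjusted p = 0.409 with an estimated correlation). Rtkn2 was 1.44-fold lower (adjusted p = 0.124), Akap5 1.66-fold lower (adjusted p = 0.148) and Ager 1.35-fold lower (adjusted p = 0.233). The score difference was -0.315 on the log2 scale (exact permutation p = 0.0159), but the groups overlapped, with XBS 3 (0.106) above MOD 5 (0.0774). Without MOD 4 and XBS 5, a choice made after seeing the data, the exact permutation p was 0.0571. By fry the alveolar type 1 list did not pass (adjusted p = 0.114). Of 13 tested endothelial genes 12 had a negative fold change (0 rose, 0 fell, 13 did not pass; 0 adjusted over the list alone; camera adjusted p = 0.00224; adjusted p = 0.617 with an estimated correlation), among them Calcrl, 1.31-fold lower (adjusted p = 0.268), and Plvap, 1.35-fold lower (adjusted p = 0.297). Their score overlapped between the groups (exact permutation p = 0.159).

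Ciliated and club cell lists were lower in XBS by camera, and 2 XBS libraries stood apart in them. The ciliated cell score stood at -1.82 in XBS 2 and -1.84 in XBS 3 and between -0.173 and 0.978 in the other 8 libraries, and the club cell score at -1.57 and -1.13 against -0.347 to 0.728. XBS 4 and XBS 5 had the highest scores of all 10 libraries for both lists, and the scores overlapped between the groups (exact permutation p = 0.365 and 0.254). The ciliated list gave camera adjusted p = 0.0104 (13 of 14 members negative; 0 rose, 0 fell, 14 did not pass; 0 adjusted over the list alone; adjusted p = 0.663 with an estimated correlation), with Tppp3 1.24-fold lower (adjusted p = 0.425). The club list gave adjusted p = 0.0116 (8 of 10 members negative; 0 rose, 1 fell, 9 did not pass; 1 lower adjusted over the list alone; adjusted p = 0.588 with an estimated correlation). Its member that fell was Cyp4b1, at 219 to 273 CPM in XBS and 377 to 406 CPM in MOD, while Scgb1a1, the main secretory protein gene of club cells, had 8525 ± 1575 CPM in MOD and 5171 ± 2871 CPM in XBS (SD, n = 5, adjusted p = 0.438). When XBS 2 and XBS 3 were left out, a choice made after seeing the data, the median log2 fold change of the ciliated list turned from -0.24 to 0.38 (adjusted p = 0.0482) and that of the club list from -0.17 to 0.06 (adjusted p = 0.439). The calls of both lists were also lost without MOD 1, XBS 2 or XBS 3 singly, with adjusted p up to 0.246 for the ciliated list and 0.0659 for the club list. With single libraries left out, the median log2 fold change of the club list ran from -0.54 to -0.067.

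**Figure D3:**
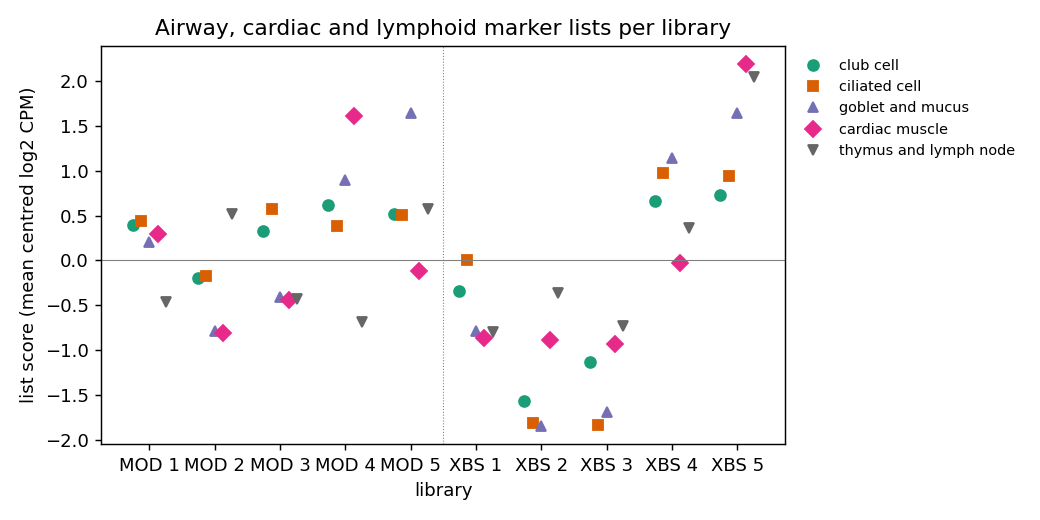
Scores of 5 marker lists (mean centred log2 CPM of the tested members) in each library, MOD to the left and XBS to the right of the dotted line, with a symbol and colour for each list. XBS 2 and XBS 3 have the lowest club, ciliated and goblet scores, MOD 4 (1.61) and XBS 5 (2.19) the highest cardiac muscle scores, and XBS 5 the highest thymus and lymph node score (2.04).

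Some lists that follow blood content, RNA composition and stress differed as well. Others did not pass by camera: mitochondrial genome, oxidative stress and NRF2, hypoxia and glycolysis, and immediate early genes (adjusted p = 0.351, 0.816, 0.512 and 0.0566). Ribosomal protein genes were higher in XBS (14 of 15 positive; 0 rose, 0 fell, 15 did not pass; 0 adjusted over the list alone; camera adjusted p = 0.00549; adjusted p = 0.644 with an estimated correlation), with a median log2 fold change of 0.18, which was 0.097 without XBS 2, where the call was lost (adjusted p = 0.0518). Red blood cell genes were lower (7 of 10 negative; 0 rose, 0 fell, 10 did not pass; 1 lower adjusted over the list alone; adjusted p = 0.0349; adjusted p = 0.588 with an estimated correlation), with Alas2, of haem synthesis, 1.56-fold lower (adjusted p = 0.143). Heat shock and unfolded protein genes were lower (12 of 15 negative; 0 rose, 0 fell, 15 did not pass; 0 adjusted over the list alone; adjusted p = 0.0462; adjusted p = 0.644 with an estimated correlation), with the chaperone gene Hsph1 1.44-fold lower (adjusted p = 0.393). Of the 10 runs without a single library, 5 lost the red blood cell call (adjusted p up to 0.0822) and 6 the heat shock call (adjusted p up to 0.154). The scores of the ribosomal protein, red blood cell and heat shock lists overlapped between the groups (exact permutation p = 0.143, 0.0952 and 0.159).

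Altogether 19 of 49 lists passed by camera, 10 higher and 9 lower in XBS, and 0 with an estimated correlation, where the smallest adjusted p was 0.148. By fry, which tests whether a list's genes move one way on balance, 7 lists passed, 5 of them among the 19. These 5 were the cell cycle, glucocorticoid response, clock positive arm, inflammasome and rhythmic output lists. The other lists past camera did not pass by fry, among them the clock negative arm and interferon response (both adjusted p = 0.232) and neutrophil markers (adjusted p = 0.285). Past fry but not camera were the interleukin 17 and xenobiotic metabolism lists (fry adjusted p = 0.048 and 0.0376). Over 21 list scores, 7 had an exact permutation p under 0.05, and 7 after adjustment. Of these 21 lists, 19 were taken because they had passed by camera on the same libraries. The adjustment therefore does not count the selection, and an adjustment over all 49 lists was not made.

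Other lists of neutrophilic and allergic inflammation, the subject of the study, did not pass by camera. Mpo, the myeloperoxidase gene of neutrophil granules, had 0 to 9 counts per library and was too low to test. The granule precursor list did not pass (6 tested, 4 positive, adjusted p = 0.472), with Lcn2 1.64-fold higher (adjusted p = 0.250) and Fcnb 1.70-fold higher (adjusted p = 0.407). Neutrophil chemoattractants did not pass (10 tested, 8 positive, adjusted p = 0.759), with Cxcl1 1.59-fold lower (adjusted p = 0.294) and Csf2 1.63-fold higher (adjusted p = 0.366). Proinflammatory cytokines did not pass (12 tested, 9 positive, adjusted p = 0.263), although adjusted over the list alone 2 were higher and 1 was lower. The cytokine gene Il1a was 2.48-fold lower in XBS (25.2 ± 9.60 against 10.2 ± 1.95 CPM, SD, n = 5, adjusted p = 0.0858), opposite to Il1b. The interleukin 17 list had 7 positive fold changes in 7 tested members, with Il17ra 1.31-fold higher (adjusted p = 0.342). It did not pass by camera (adjusted p = 0.0782, and 0.409 with an estimated correlation) but passed by fry (adjusted p = 0.048). Its score overlapped between the groups, with MOD 5 (0.189) above XBS 4 (0.0941) (exact permutation p = 0.143). Type 2 and eosinophil genes did not pass (5 of 11 positive, adjusted p = 0.816), with Il4r at a log2 fold change of -0.37 (adjusted p = 0.214) and Gata3 at 0.59 (adjusted p = 0.306), nor did goblet and mucus genes (5 of 9 positive, adjusted p = 0.514), with Bpifb1 at 156 ± 157 CPM in MOD and 105 ± 129 CPM in XBS (SD, n = 5, adjusted p = 0.837). Of NF-kB targets, Nfkbia fell and 15 of 16 did not pass (list adjusted p = 0.473). For mesothelium, adipose tissue, goblet and mucus, complement and coagulation, cardiac muscle, fibroblast and matrix, mast cell and alveolar type 2 lists, the median, the mean and the test differed in sign.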

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

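The tests of depth and of a shared effect on airway cells were chosen after their results were seen, and the cartilage genes after the airway scores but before their own values were seen. In each group of 5 libraries, a value was taken up here when its gap to the nearest library exceeded 0.71 of the group's range. Of 310 groups of values 23 met this, where chance alone gives about 15.5.

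In MOD, MOD 2 stood low for the ciliated cell score (-0.173, others 0.382 to 0.578), for the oxidative stress and NRF2 score (-0.163, others 0.0369 to 0.0865) and for Dynlrb2 (log2 CPM 5.01, others 5.61 to 5.74). MOD 5 stood high for the interleukin 17 score (0.189, others -0.229 to -0.121), Bhlhe41 (log2 CPM 4.10, others 3.20 to 3.44) and Ciita (log2 CPM 6.49, others 5.52 to 5.67) and low for Tppp3 (log2 CPM 8.50, others 8.91 to 8.99). MOD 3 was low for Bub1 (log2 CPM 3.66, others 3.90 to 3.97) and MOD 1 high for Ncapd2 (log2 CPM 4.39, others 4.14 to 4.21).

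In XBS, XBS 1 stood high for the neutrophil chemoattractant score (0.233, others -0.096 to -0.0115) and low for the mast cell score (-1.36, others 0.0584 to 0.523), Arntl (log2 CPM 4.39, others 4.99 to 5.18), Il1a (log2 CPM 2.80, others 3.38 to 3.59) and Il4r (log2 CPM 7.60, others 7.84 to 7.93). XBS 4 stood low for the interferon response score (-0.528, others 0.375 to 0.623), Irf7 (log2 CPM 6.06, others 7.53 to 7.82) and Oasl (log2 CPM 3.89, others 4.65 to 4.73). XBS 5 stood high for the cardiac muscle score (2.19, others -0.936 to -0.0351), Cd22 (log2 CPM 5.07, others 4.32 to 4.44) and Alas2 (log2 CPM 5.11, others 4.64 to 4.77). XBS 2 was high for the T cell score (0.31, others 0.0223 to 0.0913), and XBS 3 was low for Cxcl1 (log2 CPM 2.43, others 3.29 to 3.44) and for its TMM factor (0.968, others 1.01 to 1.03).

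XBS 2 and XBS 3 had the lowest ciliated and club cell scores of all libraries. Shallower sequencing is argued against for XBS 3, whose total (15343515 counts) lay above the median of the other 8 (13970000). The total of XBS 2 (13354887 counts) lay below that median, so its total does not decide the question for XBS 2. The shallowest library, XBS 1 (11998979 counts), had a ciliated score of 0.00221 and a club score of -0.347. An effect on airway cells shared by the 5 XBS libraries cannot be told apart from other causes. Of XBS 1, XBS 4 and XBS 5, 2 had both scores at or above the lowest MOD library. These were XBS 4 and XBS 5, which lay above every MOD library in both, opposite to a shared lowering. The club score of XBS 1 (-0.347) lay below every MOD library (lowest -0.2). The club cell gene Cyp4b1 was lower in all 5 XBS libraries but did not follow the club score. XBS 5, with the highest club score (0.728), had the lowest Cyp4b1 (219 CPM), and XBS 2, with the lowest (-1.57), had 258 CPM. Between the groups the exact permutation p was 0.365 for the ciliated and 0.254 for the club score. An effect in some animals was not tested. Less conducting airway in the tissue piece may account for the pattern but stays open. The cartilage score was lowest in XBS 3 (-0.497), but XBS 2 (-0.265) lay above MOD 2 (-0.267) and MOD 4 (-0.297). It stood 0.0318 above the lowest of the other 8 libraries, and only 4 of 12 cartilage genes could be tested.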

How the results depend on the processing

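Leaving out XBS 2 and XBS 3, leaving out MOD 4 and XBS 5, an adjusted p under 0.1 and the airway covariate were chosen after seeing the data. The causes of the changes given here were not tested, beyond the fewer libraries or other thresholds that an alternative has by its making. Of the values for single named genes under the alternatives, 1823 kept their direction and their side of the threshold, 89 lost the threshold, 32 gained it and 14 changed sign; for lists the numbers were 324, 88, 0 and 8, and for list scores 282, 2, 6 and 4. Depth limits the low genes, such as Mpo, which could not be tested.

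RLE and upper quartile scaling and both filters gave 10 or 11 genes, and 10 or 11 of them were among the 11. DESeq2 gave 348 genes, 202 higher and 146 lower, and limma voom with sample weights 66, 42 higher and 24 lower, each with all 11 among them. With at least a 2-fold change added, 4 genes passed the adjusted threshold, 1 higher and 3 lower, and 85 an unadjusted p under 0.05, 55 higher and 30 lower. An adjusted p under 0.1 gave 67 genes, 38 higher and 29 lower. Without XBS 2 and XBS 3, 3 genes passed, 0 higher and 3 lower, 2 of them among the 11. Without MOD 4 and XBS 5, edgeR gave 0 genes, 0 higher and 0 lower, with 1340 at an unadjusted p under 0.05. With the airway score as a covariate 6 genes passed, 0 higher, 4 of them among the 11, with 1778 at an unadjusted p under 0.05. Leaving out each library in turn gave 4 to 15 genes, 0 to 6 higher and 4 to 9 lower; the total was 5 without MOD 2, 7 without MOD 3, 4 without MOD 4, 5 without XBS 1, and 4 without XBS 2 or XBS 3.

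The log2 fold change of Nr1d1 was 2.44 to 3.15 with single libraries left out. It passed by DESeq2 (2.70, adjusted p = 7.13e-09), by limma voom (2.68, adjusted p = 0.0362) and without MOD 3 (3.15, adjusted p = 0.0213); over all its alternatives the adjusted p ran from 7.13e-09 to 0.226. Lists past the threshold numbered 0 by camera with an estimated correlation and 7 by fry, against 13 to 22 otherwise. Calls of lists were lost without MOD 1 (monocyte and interstitial macrophage), XBS 2 (ribosomal proteins), MOD 1, XBS 2 or XBS 3 (ciliated, club and neutrophil lists), MOD 1, MOD 3, MOD 4, XBS 1 or XBS 4 (red blood cell), MOD 3, MOD 4, MOD 5, XBS 2 or XBS 5 (B cell), MOD 1, MOD 2, MOD 3, MOD 4, XBS 3, XBS 4 or XBS 5 (dendritic cell), MOD 1, MOD 4, XBS 2, XBS 3, XBS 4 or XBS 5 (T cell), and MOD 2, MOD 4, MOD 5, XBS 1, XBS 3 or XBS 5 (heat shock). The clock arms difference kept an exact p under 0.05 at 1.03 to 1.55 in all alternatives except the replicate block.

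The libraries of both groups share only a replicate number. Same-numbered libraries had correlations of 0.329, 0.215, -0.125, 0.0915 and 0.201, and 2 of 10 libraries correlated best with their own number. With the replicate block edgeR gave 1 gene, 0 higher and 1 lower, 0 of it among the 11, with 2070 at an unadjusted p under 0.05, and 22 lists. The clock arms difference over same-numbered pairs was 1.21 with an exact sign-flip p of 0.0625, the smallest that 5 pairs allow. The median of the neutrophil granule precursor list was -0.046 with the block.

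Signs that changed belonged to values not past their threshold, except for the ciliated and club lists. Without XBS 2 and XBS 3 the log2 values were 0.30 for Usp2, 0.18 for Dynlrb2, 0.23 for Dnai1, 0.0021 for Aldh1a1, 0.11 for Bpifb1, 0.38 and 0.057 for the medians of the ciliated and club lists and 0.29 and 0.18 for their scores. Without MOD 4 and XBS 5 they were -0.027 for Ccdc39 and -0.29 for Foxa3. With the airway covariate they were 0.15 for Usp2, 0.093 for the ciliated list and -0.029 for the granule precursor list. The covariate is built in part from the ciliated score, so the value for the ciliated list is not independent of it. The neutrophil chemoattractant score was -0.026 with the median over members. With single libraries left out, ranges that crossed 0 were -1.34 to 0.20 for Bpifb1, -0.45 to 0.038 for Usp2, -0.058 to 0.31 for Bhlhe41, -0.0084 to 0.36 for Ccdc39, -0.066 to 0.80 for Foxa3, -0.56 to 0.029 for the ciliated list, -0.0028 to 0.17 for the chemoattractant list and -0.027 to 0.057 for its score.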

Other observations

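The tests of the clock arms without XBS 2 and XBS 3, of the time of day, of cell cycle scores and of gene counts over other splits by edgeR were chosen after the results were seen, as were the gene ontology terms. Terms attached to the genes in the deposited table were tested by camera; 55 of 2895 terms with 10 to 300 tested genes passed, 33 higher and 22 lower in XBS, and 0 with an estimated correlation (adjusted p = 0.842 or above for those named here). Mitotic sister chromatid segregation (20 genes, median log2 fold change 0.33, adjusted p = 2.2e-05), kinetochore assembly (12 genes, 0.53, adjusted p = 0.000117) and defense response to virus (106 genes, 0.18, adjusted p = 0.00343) were higher. Platelet-derived growth factor receptor signalling (33 genes, -0.22, adjusted p = 0.00295) and adherens junction (90 genes, -0.14, adjusted p = 0.00347) were lower.

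Lists of clock and glucocorticoid genes differed between the groups by camera, though not with an estimated correlation. Less airway tissue in XBS 2 and XBS 3 is argued against as the cause of the clock difference. These 2 libraries had the lowest clock arms values in XBS (-0.0157 and 0.213), so the difference was larger without them, at 1.55. The test covered the clock arms alone. Lower glucocorticoid signalling in XBS lungs is a candidate explanation: of 18 further glucocorticoid targets, chosen before their values were seen, 15 had a negative fold change, with a median log2 fold change of -0.20 (fry p = 0.00082, a model across all 10 libraries rather than an exact test), although 0 passed over all genes. A different time of day at collection cannot be told apart from another difference between the groups, since the positive arm score differed by -0.541 while the negative arm differed by 0.671 and the labels give no time of collection. Hormone level and time of day also vary together in rats, so that these explanations may overlap.

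The score of the cell cycle list was higher in every XBS library than in any MOD library, though the list did not pass with an estimated correlation (adjusted p = 0.148). Lymphoid tissue in the XBS 5 piece is argued against as the whole cause, since the score difference was 0.441 without that library, against 0.456 with it and a pooled SD of 0.147 within groups. Less airway tissue in XBS 2 and XBS 3 is likewise argued against, with a difference of 0.466 without them. Whether more cells divided, and which, was not tested.

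Over 100 splits of the libraries, 1 gave as many as 11 genes by edgeR, the real one, and the highest of the others gave 1. In each direction, 1 split, the real one, gave as many as 4 genes higher or 7 genes lower, again with at most 1 in the others. These counts lay above those of every other split tested, which argues against chance without excluding it, as the test was chosen afterwards. For lists past the camera threshold, 3 of 100 splits, the real one included, gave as many as the real 19. The highest of the others gave 20 and their median was 12. The number was thus seldom reached but lay within the range of the other splits, so chance cannot be excluded for it. Single lists were not tested over splits. For DESeq2, 2 of 40 splits gave as many as the real 348 genes, so chance cannot be excluded for that count. The other split, which differs from the real one by the exchange of MOD 1 and XBS 4, gave 1344 genes by DESeq2 and 0 by edgeR; whether the larger number points to a structure of the samples or to the tool was not tested.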
